A study of Mus musculus with 7 samples.

How the data were processed

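Total RNA was prepared from sorted OT-I CD8+ T cells with a kit, and 6 µg per sample was labelled with biotin and hybridised to Affymetrix mouse arrays, per the labels' protocols. The authors deposited 1 table of log2 values for 45101 probe sets on 7 arrays. The submitters' processing notes name RMA, which corrects background, normalises arrays by quantiles and summarises the probes of a probe set, and limma; their versions are not given in the sources used here. The deposited log2 values were used without further normalization. RMA makes arrays that were processed together share nearly the same sorted values. Here the sorted values of the 4 MPEC arrays differed by at most 0.042 on average, those of the 2 CD27hi arrays by 0.0646, those of a CD27hi and an MPEC array by at least 0.797 and those of the SLEC array and an MPEC array by at least 0.407. The array medians were 6.67 and 6.64 for the CD27hi arrays, 5.75, 5.79, 5.74 and 5.80 for the MPEC arrays and 5.28 for the SLEC array. The 3 sets thus appear to have been normalised apart, and any level set across them carries that difference. No 2 arrays held the same values throughout.

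Groups were taken from the sample titles and characteristics. There was 1 array each of CD27hi wild-type, CD27hi Foxo1 knockout and wild-type SLEC, and 2 each of wild-type and knockout-labelled MPEC. Day 7 of infection is stated for the CD27hi sort.

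Probe sets were named from GEO's platform annotation, which can be old. Of the probe sets 64 were controls and were left out, 34945 had 1 gene symbol, 932 had several and 9160 were not listed. Of probe sets with 1 symbol, the one with the highest mean over the 7 arrays stood for its gene. This gave 18193 genes, of which the 7277 with a mean under the 40th percentile (5.97 log2) were left out and 10916 were tested. Where another probe set of a named gene above the filter went the opposite way by over 0.5 log2 in a comparison that states its direction, the text says so.

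The tests were limma 3.58.1 linear models with empirical Bayes moderation in R 4.3.3, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05, as two-sided moderated tests. The MPEC and SLEC contrasts and the difference of the knockout effects came from a fit of 5 group means over the 7 arrays, whose 2 residual degrees of freedom come from the MPEC arrays. The fit over both sorts used the 6 KLRG1lo arrays with the sort as a block and has 3. The CD27hi pair has 1 array per genotype and was described by size alone, with 2-fold as the threshold. SLEC differences are given after subtracting the median difference of all genes. Their p-values, the list tests and the adjustments over a list alone come from the unshifted values.

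Gene lists, 24 in number, were written before the data were examined. They hold 491 genes, of which 51 had no probe set of 1 symbol and 385 passed the filter. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the lists. In the CD27hi pair a list's median was ranked among 10000 random lists of the same size matched on mean expression. The lists include markers of B, myeloid, NK, CD4, erythroid and platelet cells that a sort can let through.

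Named genes follow a rule fixed before the data were examined: Foxo1, Klrg1, Cd27 and Il7r always; in the MPEC, both-sorts and SLEC comparisons the 10 largest differences in each direction with no overlap of arrays (over both sorts, the same direction in all 3 pairs), given as values where they did not pass the test; and up to 4 members per list with the smallest p. The same rule of size was applied to the CD27hi pair after the data had been seen, and the list members named are a subset of those the rule gives, chosen after their values were seen. Because no gene passed in the SLEC contrast, the 100 largest differences in each direction took the place of called genes, and because none passed in MPECs, genes at 2-fold or more without overlap took their place in the comparison of signs. The bounds of the tests in the closing section were set after the values had been seen.

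The fits were tested on simulated arrays with known changes at the spread of the MPEC fit. With 10916 genes the MPEC contrast recovered 0% of genes changed 2-fold, 42% of those changed 4-fold, 68% of those changed 8-fold and 82% of those changed 16-fold. The SLEC contrast recovered 0%, 42%, 60% and 70%, and the fit over both sorts 44%, 64%, 90% and 94%. With every gene at the median spread within pairs, the MPEC contrast and the fit over both sorts each recovered 100% of genes changed 2-fold, but with each gene at its own spread within pairs and the real replicate shift the MPEC contrast recovered 0% of genes changed 2-fold and 40% of those changed 4-fold. The effector list, shifted by 1 log2 in the MPEC contrast, was called (adjusted p = 7.1e-27), and so were 3 other lists. Some lists share genes with the shifted one, such as Gzmb in the cytotoxic granule list, so these 3 calls need not be false. In the real data no call held with an estimated correlation, so a preset-correlation call alone is taken as weak evidence for a list.

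The alternatives were no filter and a filter at the 60th percentile, the mean of all probe sets of a gene, each probe set by itself, quantile normalization of all 7 arrays, centring each array on its median, an intensity trend in the moderation, fits with the replicate number as a block, fits without the sort block, other fold thresholds, the spread of the wild-type MPEC arrays alone, and leaving out each MPEC array. Where this leaves 1 array in a group, that array is assumed to vary like the others. The sex of the arrays as a block in the SLEC contrast was added after the data were seen.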

Results

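Genome-wide expression was measured on 7 Affymetrix mouse arrays from OT-I CD8+ T cells, transgenic T cells that recognise an ovalbumin peptide. The cells had responded to Listeria that expressed ovalbumin, and the CD27hi cells were sorted on day 7 of the infection. One sort held CD27hi KLRG1lo cells, with 1 wild-type array and 1 array of cells in which a granzyme B-driven Cre recombinase acts on a floxed Foxo1 gene. The other sort held KLRG1lo memory precursor effector cells (MPECs), with 2 wild-type and 2 knockout-labelled arrays, and KLRG1hi short-lived effector cells (SLECs), with 1 wild-type array. Foxo1 is a forkhead transcription factor that drives genes of T cell quiescence, homing and memory. The number of arrays limits the precision of every value. The labels do not say whether replicates came from separate mice, so p-values measure only the spread between these arrays.

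Foxo1 itself was read by 3 probe sets above the expression filter. In the CD27hi sort its log2 signal was lower in the knockout array, by -2.36, -2.35 and -2.35. The MPEC arrays are set in pairs by the replicate number of their labels. In MPEC pair 1 the differences were -0.88, -0.44 and -0.48, but in MPEC pair 2 they were 0.46, 0.45 and 0.51, against the label. On the brightest probe set the wild-type MPEC arrays read 11.18 and 9.66 and the knockout-labelled MPEC arrays 10.70 and 10.17. Where these probe sets lie relative to the deleted part of the gene is not given in the sources used here. They did read lower in the CD27hi knockout array, so their position alone leaves the MPEC values unexplained. Whether Foxo1 was deleted in the MPEC arrays stays open. The titles of these MPEC arrays read Foxo1fl/fl and name no Cre recombinase, so the titles do not state a deletion. The arrays are therefore called knockout-labelled throughout, and every direction drawn from them rests on reading that label as a knockout. The sort marker Klrg1, an inhibitory receptor of terminal effector cells, read 6.86 and 7.27 in the CD27hi arrays, between 9.91 and 10.7 in the MPEC arrays and 13.3 in the SLEC array. Cd27, a costimulatory receptor, read 10.78 and 11.23 in the CD27hi wild-type and knockout arrays. The 3 sets of arrays appear to have been normalised apart, so levels are not ranked across them.

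The 2 replicates of the MPEC sort differed in more than genotype. Xist, the RNA of the inactive X chromosome, read 13.05 and 13.08 on the MPEC arrays numbered 2 and at most 6.71 on the other 5, and the Y-linked Eif2s3y showed the reverse, with 3.51 and 3.49 against values of at least 10.4. The 20 measured myeloid marker genes had a median 1.51 log2 higher in replicate 2 than in replicate 1 of the wild-type MPECs and 2.70 higher in the knockout-labelled MPECs, and the 15 T cell identity genes had medians of -0.70 and -0.55.

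**Figure D1:**
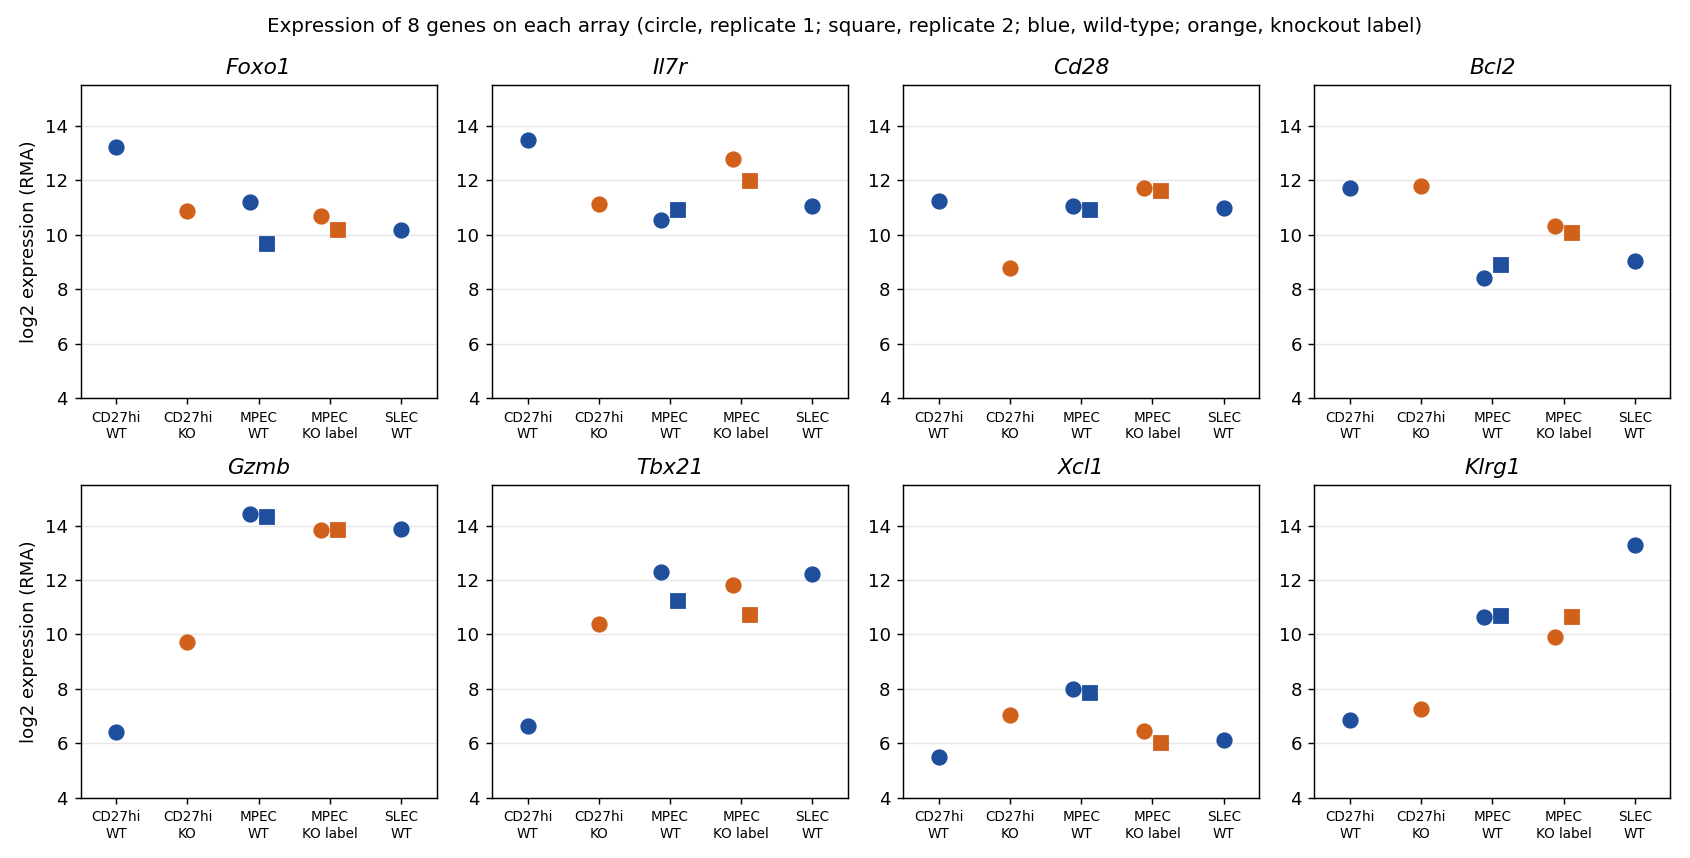
Log2 expression (y axis) of 8 genes on each of the 7 arrays (x axis, by group); circles are replicate 1, squares replicate 2, blue wild-type and orange knockout label. Foxo1 and Il7r were both lower in the CD27hi knockout array (by -2.35 and -2.35), while Il7r was higher in both knockout-labelled MPEC arrays than in both wild-type MPEC arrays.

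The first comparison asked how CD27hi KLRG1lo cells differ without Foxo1. In this pair Il7r, the interleukin-7 receptor that sustains memory T cells, had a log2 difference (knockout minus wild-type) of -2.35. Cd28, the costimulatory receptor of T cells, had -2.47, Cd55, a complement regulator, -3.68, Dapl1 -2.94 and H2-Ob, a chain of an MHC class II chaperone, -4.79. Genes of effector function lay the other way, with Gzma at 4.05, Gzmb at 3.30, Tbx21, which encodes the effector transcription factor T-bet, at 3.75 and Irf8 at 2.72. In the wild-type array Gzma, Gzmb and Tbx21 read 6.77, 6.43 and 6.62, against 10.8, 9.73 and 10.4 in the knockout array. From single arrays a change within cells cannot be told from a different mix of cells. The chemokine Xcl1 was at 1.53, and the sort markers Klrg1 and Cd27 were at 0.41 and 0.45. In all, 204 of 10916 genes differed by 2-fold or more, 127 of them higher and 77 lower in the knockout array. The largest positive differences were 5830411N06Rik at 5.27 and Tgm2, a transglutaminase, at 4.73, followed by those of Gzma, Tbx21 and Gzmb and by Igha at 2.85, Jchain at 2.84, Iigp1 at 2.82, Irf8 and Hemgn at 2.68. After H2-Ob and Cd55 the largest negative ones were Slc6a19 at -3.53, App at -3.52, Ms4a6c at -3.41, Vipr1 at -3.39, Sntb1 at -3.05, Dapl1, Cd28 and Il7r. For Ms4a6c 1 other probe set went the opposite way. The lower array of Jchain, Hemgn, H2-Ob, Cd55 and Sntb1 read under 5.97, the level of the expression filter, so their sizes and ranks are not exact. That level is set over all 7 arrays, and the CD27hi wild-type and knockout arrays had medians of 6.67 and 6.64. The lower arrays of Gzmb, Tgm2, 5830411N06Rik, Tbx21, Slc6a19 and App read under their own array's median, so their sizes may not be exact either. With 1 array per genotype these differences have no replicate check.

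The median difference over all genes of this pair was 0.09. Of 34 measured cell cycle genes all 34 were higher in the knockout array, with a median of 0.52, and of 27 interferon response genes all 27 were higher, with a median of 0.46. Examples are Top2a at 0.92 and Ube2c at 0.73 in the cell cycle list, and Gbp3 at 1.33 and Gbp2 at 1.22 in the interferon list. The effector list had a median of 0.39, with 22 of its 36 genes higher and 14 lower, 11 and 2 of them by 2-fold or more. The stress and immediate early list had a median of 0.39, with 20 of 22 genes higher, and the list of cytokine receptors and signalling regulators 0.47, with 21 higher and 7 lower. The medians of these 5 lists lay at percentile 100 of 10000 random lists matched on size and mean expression. The list of Foxo1 target genes of T cells had a median of -0.06 at percentile 0.03, and 10 of its 25 genes were higher and 15 lower, among them Il7r, Sesn1 at -1.10 and Trib2 at -1.01. The memory list did not move as 1 group (median 0.19, percentile 92.8), since Il7r and Cd28 lay low while Xcl1 and Bcl6 (1.51) lay high.

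The replicated comparison set the knockout-labelled MPEC arrays against the wild-type MPEC arrays. Il7r and Gpr183, low in the CD27hi knockout array, lay high here. Slc15a2 (1.03) had been higher there too, while Bcl2 (0.07) had lain near the median of all genes in that pair (0.09). Il7r had a mean log2 difference of 1.65 ± 0.35 (SE, n = 2 per group), Bcl2, which blocks apoptosis, 1.52 ± 0.24, and Gpr183, an oxysterol receptor that guides lymphocyte position, 1.52 ± 0.23. Slc15a2, a peptide transporter, had 3.33 ± 0.97, Slc25a33 1.73 ± 0.46, Trat1 1.68 ± 0.76, Hs3st3b1 1.64 ± 0.74, Wfikkn2 1.55 ± 0.51 and Tnfrsf25 1.52 ± 0.71. The heat shock gene Hspa1a, with 1.63 ± 0.86, owed its value mostly to pair 2, at 2.96 against 0.31 in pair 1. The largest negative values were those of the chemokine Xcl1 at -1.70 ± 0.22, Filip1 at -1.35 ± 0.35, P2rx7, an ATP-gated channel, at -1.33 ± 0.38, Erdr1 at -1.12 ± 0.47, the receptor Cd160 at -1.11 ± 0.38, Sema7a at -1.08 ± 0.17, Tbc1d2 at -0.98 ± 0.23, Itih5 at -0.96 ± 0.18, Il2ra, the high-affinity interleukin-2 receptor chain, at -0.95 ± 0.21 and Zfp512 at -0.93 ± 0.27. The wild-type means of Trat1 (5.30) and Hs3st3b1 (5.71) lay under the level of the expression filter. All 20 had non-overlapping arrays, but leaving out 1 array shrank 10 of these values by more than 1.5 times. Without knockout-labelled replicate 1 Trat1 was at 0.78, Hs3st3b1 at 0.70, Wfikkn2 at 0.86 and Erdr1 at -0.61, and without knockout-labelled replicate 2 Hspa1a was at 0.43 and Cd160 at -0.67. Without wild-type replicate 1 Slc15a2 was at 1.97, P2rx7 at -0.85 and Zfp512 at -0.61, and without wild-type replicate 2 Tnfrsf25 was at 0.71. Over all genes, 1751 of 10916 (16.0%) had no overlap, where chance gives 33.3%.

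No single gene passed the test. With limma 0 of 10916 genes had an adjusted p under 0.05 (smallest adjusted p = 1), and 101 had an unadjusted p under 0.05. Arrays of the same genotype differed in sex and myeloid content, and any difference between replicates widens the spread in this test and in the standard errors and adds to the overlap of arrays. The test and standard errors given here do not take out the replicate number. With it as a block in limma 0 genes passed too (smallest adjusted p = 0.547), but 946 had an unadjusted p under 0.05. The lack of single genes is therefore no evidence that the label made no difference. By size, 116 genes differed by 2-fold or more in pair 1 and 66 in pair 2. Both pairs shared 14 of them in the same direction, 11 higher and 3 lower, and 1 in opposite directions.

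Among the 24 gene lists 11 were called in this comparison by camera with a preset correlation of 0.01, and none with an estimated correlation (smallest adjusted p = 0.527 with an estimated correlation). The Foxo1 target list was higher in the knockout-labelled arrays (median 0.33, adjusted p = 4.6e-13), with 18 of 25 genes higher and 2 lower in both pairs. Its leading members were Trib2 at 1.33 ± 0.22, Il7r, Bcl2l11, a pro-apoptotic gene, at 0.64 ± 0.19 and Sesn1 at 0.63 ± 0.17. The memory list was higher too (median 0.26, adjusted p = 1.8e-07), with Bcl2, Il7r and Cd28 (0.70 ± 0.17) on the high side and Xcl1 on the low side. Adjusted over the list alone 2 of its members passed, Bcl2 on the high side and Xcl1 against the direction of the list. The Foxo1 target and memory lists were the 2 lists whose calls held without each of the 4 MPEC arrays in turn. The effector list (median -0.14, adjusted p = 0.0019) and the cytotoxic granule list (median -0.26, adjusted p = 0.00565) were lower, with Gzmb at -0.54 ± 0.15, Lgals3 at -0.41 ± 0.20, Anxa2 at -0.38 ± 0.16, Gzma at -0.32 ± 0.18 and Serpinb9 at -0.32 ± 0.20. The effector call was lost without knockout-labelled replicate 1 (adjusted p = 0.222) or wild-type replicate 1 (adjusted p = 0.298), and the granule call without knockout-labelled replicate 2 (adjusted p = 0.108) or wild-type replicate 1 (adjusted p = 0.0786). Cytokines and chemokines (median -0.26, adjusted p = 0.00565), led by Xcl1 and Tnfsf9 (-0.44 ± 0.19), and inhibitory receptors (median -0.19, adjusted p = 0.024), led by Havcr2 at -0.89 ± 0.20 and Cd160, were lower as well, although Btla was at 0.45 ± 0.20. The cytokine call was lost without knockout-labelled replicate 1 (adjusted p = 0.192) or wild-type replicate 1 (adjusted p = 0.0536), and the receptor call without replicate 2 of the knockout-labelled (adjusted p = 0.220) or wild-type (adjusted p = 0.480) arrays. Adjusted over the list alone in this fit without a replicate block, 1 cytokine passed and no member of any other list but the memory list. That cytokine was Xcl1, which the memory list holds as well.

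The called cell cycle, stress and B cell lists had medians that differed in size or sign between the 2 pairs. Cell cycle genes were lower on average (adjusted p = 0.00565), with medians of 0.01 in pair 1 and -0.43 in pair 2; Top2a was at -0.25 ± 0.30 and Ube2c at -0.33 ± 0.31. Stress and immediate early genes were higher (adjusted p = 0.024), with medians of -0.04 and 0.36; here Hspa1b was at 1.43 ± 0.69 and Egr3 at -0.69 ± 0.19. The cell cycle list was on average higher without knockout-labelled replicate 1 (adjusted p = 0.115) or wild-type replicate 2 (adjusted p = 4.5e-07). The stress list was on average lower without knockout-labelled replicate 2 (adjusted p = 0.00319) or wild-type replicate 1 (adjusted p = 0.649). B cell markers were lower (adjusted p = 0.024), with medians of -0.76 and 0.26, Ms4a1 at -1.42 ± 1.22 and Cd74 at -0.54 ± 0.97. They were on average higher without knockout-labelled replicate 1 (adjusted p = 0.0564), and the call was lost without wild-type replicate 2 (adjusted p = 0.297). Myeloid markers, which were not called (adjusted p = 0.358), had medians of -1.11 and 0.29, with S100a8 at -0.99 ± 1.55. With an estimated correlation the adjusted p of the cell cycle and stress lists was 0.850 and that of the B cell list 0.754. Survival genes, with medians of 0.05 and 0.09 in the pairs, were higher (median 0.05, adjusted p = 0.0243; adjusted p = 0.527 with an estimated correlation), led by Bcl2, Bcl2l11 and Pim2 (0.93 ± 0.46), and CD4 and regulatory T cell markers, with -0.08 and -0.10, lower (median -0.08, adjusted p = 0.0243), led by Il2ra. The survival call held only without wild-type replicate 1, and the CD4 call was lost without each of the 4 arrays (highest adjusted p = 0.322). The other 12 lists were not called, with adjusted p from 0.0885 for homing and egress receptors (adjusted p = 0.0483 after quantile normalization of the 7 arrays), where Ccr7 was at 1.24 ± 0.49 and Ccr9 at -1.76 ± 0.89, to 0.818 for sex-linked genes and for cytokine receptors and signalling regulators. Between these lay glycolysis, fatty acid oxidation and lysosome, interferon response, NK cell receptors, NK cell markers, transcription factors of CD8 T cell fate (Batf3 at -0.86 ± 0.18, Maf at 0.61 ± 0.20), T cell identity, ribosomal proteins, and erythroid and platelet markers.

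**Figure D2:**
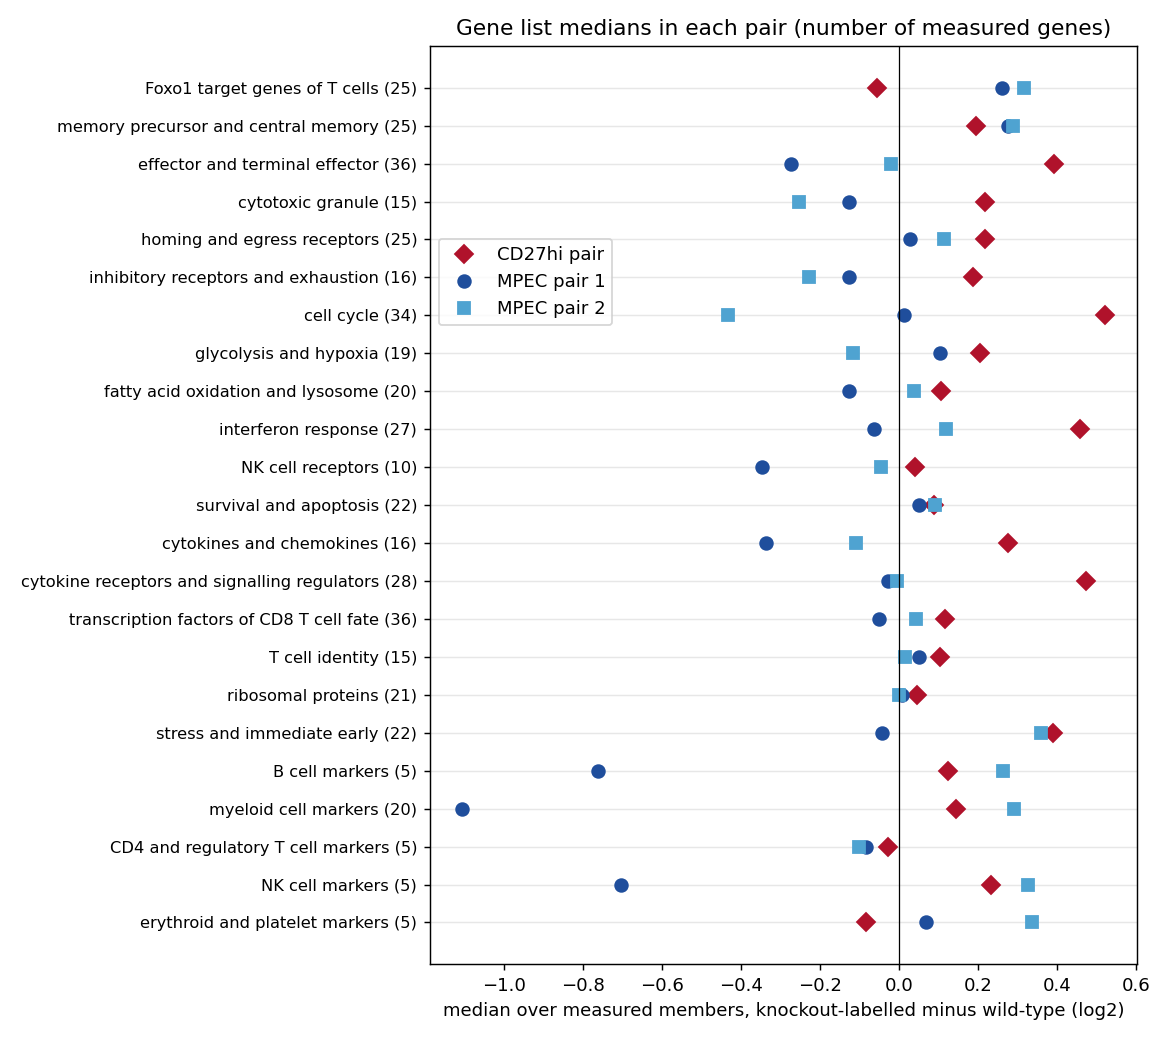
Median log2 difference, knockout-labelled minus wild-type (x axis), over the measured members of 23 gene lists (y axis, number of genes in parentheses) in the CD27hi pair (diamonds), MPEC pair 1 (circles) and MPEC pair 2 (squares). The Foxo1 target list lay at -0.06 in the CD27hi pair and at 0.26 and 0.32 in the MPEC pairs, while the myeloid list lay at -1.11 in MPEC pair 1 and 0.29 in pair 2.

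The 2 sorts were then compared for their knockout differences. Some genes that lay low in the CD27hi knockout array, Il7r, Trat1 (-1.63), Gpr183 (-1.79) and Trib2 among them, lay high in the knockout-labelled MPECs, and some that lay high, among them Xcl1, Cd160 (1.64), Gzmb and Irf8 (-0.58 in MPECs), lay low. Others lay the same way in both sorts, with Epas1 (-0.86 in the CD27hi pair and -0.66 in MPECs) low and Hspa1b (2.43 in the CD27hi pair) and Maf (1.22 in the CD27hi pair) high. App, low in the CD27hi pair, was at -1.62 in MPEC pair 1 but at 0.18 in pair 2. Across genes, which are not independent replicates, the differences had a Pearson correlation of -0.219 and a Spearman correlation of -0.107. Against pair 1 alone the Pearson correlation was -0.234, and against pair 2 alone -0.104. It was -0.0659 without knockout-labelled MPEC replicate 1, -0.133 without wild-type replicate 1 and -0.127 without wild-type replicate 2. Of the 30 genes that differed by 2-fold or more on average between MPEC genotypes with no overlap of arrays (24 higher, 6 lower), 23 (76.7%) had the opposite sign in the CD27hi pair, against 53.7% of all genes. Between the MPEC pairs the correlation was 0.235. The difference of the 2 effects, tested with limma on the assumption that the CD27hi arrays vary like the MPEC arrays, gave 0 of 10916 genes past the threshold (smallest adjusted p = 0.313), with 205 at an unadjusted p under 0.05.

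**Figure D3:**
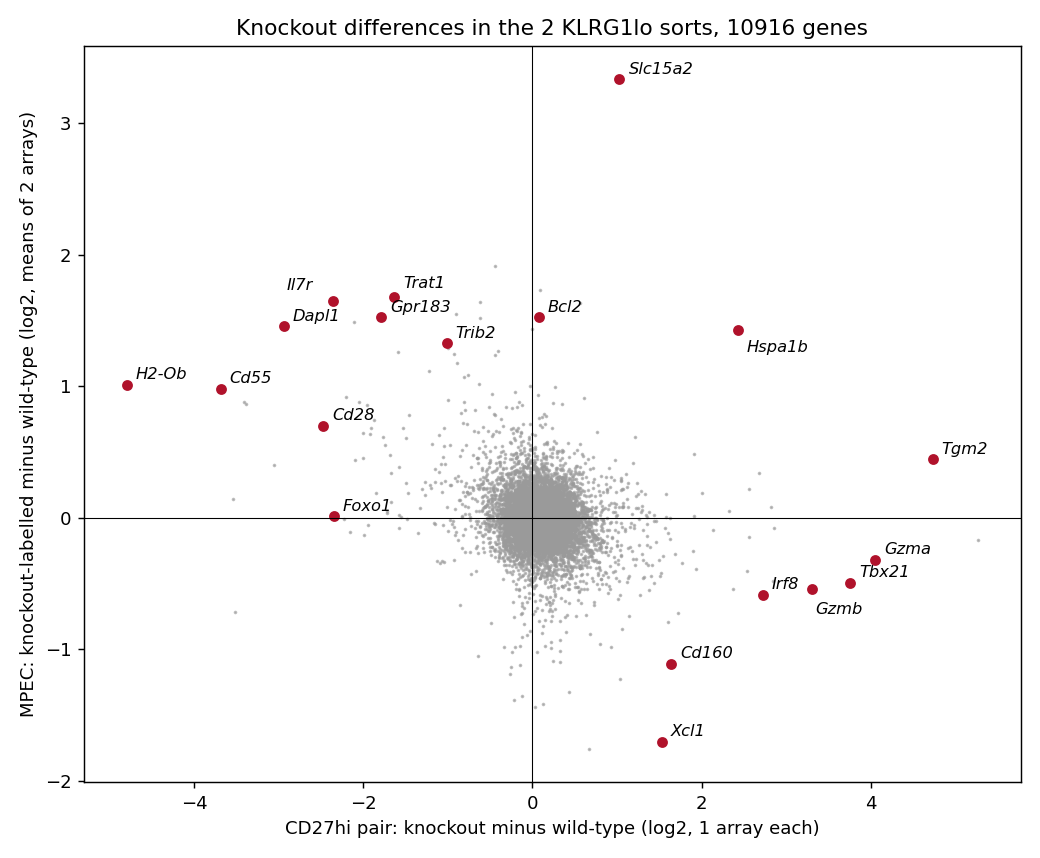
Log2 difference of each of 10916 genes between knockout and wild-type in the CD27hi pair (x axis, 1 array each) and between knockout-labelled and wild-type MPECs (y axis, means of 2 arrays); red points are named genes. Il7r lies at -2.35 and 1.65 and Xcl1 at 1.53 and -1.70, on opposite sides of 0 on both axes.

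Taken over both sorts with the sort as a block, the genes that lay the same way in all 3 pairs were led by Slc15a2 at 2.56 ± 0.83 (SE, n = 3 per group), Hspa1b at 1.76 ± 0.53, Hspa1a at 1.28 ± 0.65, Slc25a33 at 1.19 ± 0.47, Bcl2 at 1.04 ± 0.34, Jun at 0.96 ± 0.95, Maf at 0.81 ± 0.19, Septin8 at 0.81 ± 0.89, Nsg2 at 0.75 ± 0.45 and Bach2, a transcription factor of memory T cells, at 0.70 ± 0.26. On the low side were Lcn2 at -0.99 ± 1.40, Filip1 at -0.94 ± 0.35, Ddit4 at -0.92 ± 0.60, Chil3 at -0.88 ± 1.70, Ngp at -0.84 ± 1.32, Erdr1 at -0.79 ± 0.39, Itga4 at -0.79 ± 0.45, S100a8 at -0.77 ± 1.11, Epas1 at -0.73 ± 0.13 and Tbc1d2 at -0.70 ± 0.24. Lcn2, Chil3, Ngp and S100a8 are transcripts of granulocytes. For Lcn2, Chil3 and S100a8 both CD27hi arrays read under 5.97, the level of the expression filter, so their sign in that pair may be background. Bcl2 (0.07) and Slc25a33 (0.09) differed little in the CD27hi pair. Foxo1 was at -0.78 ± 0.63, Il7r at 0.32 ± 0.85, Klrg1 at -0.13 ± 0.27 and Cd27 at 0.00 ± 0.28. With limma 0 of 10916 genes had an adjusted p under 0.05 (smallest adjusted p = 0.9999), and 63 had an unadjusted p under 0.05.

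Over both sorts 7 lists were called by camera with the preset correlation and none with an estimated correlation (smallest adjusted p = 0.758 with an estimated correlation). Higher in the knockout label were interferon response genes (median 0.19, adjusted p = 2.5e-04), with Gbp3 at 0.56 ± 0.31, Gbp2 at 0.52 ± 0.25, Rtp4 at 0.44 ± 0.27 and Oas1a at 0.31 ± 0.15, and stress genes (median 0.24, adjusted p = 6.1e-04), with Junb at 0.59 ± 0.24 and Gadd45b at 0.54 ± 0.23. The Foxo1 targets (median 0.21, adjusted p = 4.3e-04), the memory list (median 0.21, adjusted p = 0.00713) and survival genes (median 0.12, adjusted p = 0.0335) were higher, with Lef1 at 0.33 ± 0.15, Bcl2l11 at 0.39 ± 0.21 and Pim2 at 0.64 ± 0.37. B cell markers (median -0.15, adjusted p = 0.0448; Ms4a1 at -0.90 ± 0.92) and CD4 and regulatory T cell markers (median -0.10, adjusted p = 0.0373; Cd40lg at -0.10 ± 0.12, Cd4 at -0.06 ± 0.14) were lower. These calls average pairs that did not always agree. In the CD27hi pair, MPEC pair 1 and MPEC pair 2 the medians were 0.46, -0.06 and 0.12 for interferon response, 0.39, -0.04 and 0.36 for stress, -0.06, 0.26 and 0.32 for Foxo1 targets, 0.19, 0.28 and 0.29 for memory, 0.09, 0.05 and 0.09 for survival, 0.12, -0.76 and 0.26 for B cell markers and -0.03, -0.08 and -0.10 for CD4 markers. No list had a member past the threshold when adjusted over the list alone. The B cell and CD4 calls were lost after quantile normalization of the 7 arrays (adjusted p = 0.101 each). The interferon call was lost without wild-type MPEC replicate 2 (adjusted p = 0.0741), the Foxo1 target call without that array (adjusted p = 0.266) or knockout-labelled replicate 1 (adjusted p = 0.163), and the stress call without wild-type replicate 1 (adjusted p = 0.296) or knockout-labelled replicate 2 (adjusted p = 0.781, on average lower). The memory and B cell calls each held without 1 of the 4 MPEC arrays, and the survival and CD4 calls were lost without any 1 of them. Without wild-type MPEC replicate 2 the count of lists was 3, and without wild-type MPEC replicate 1 it was 4.

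Wild-type SLECs were set against wild-type MPECs to describe the terminal effector state. The SLEC array appears to have been normalised apart from the MPEC arrays. Its median difference over all genes was -0.28, so differences are given relative to that shift. SLECs had 2.88 ± 0.36 (SE, 1 array against 2) for Klrg1, 2.17 ± 0.21 for Cx3cr1, a chemokine receptor of effector cells in blood, 2.63 ± 0.96 for S1pr5, a receptor of egress, and 2.38 ± 0.61 for Klre1. Other large values were those of Slc15a2 at 3.69 ± 1.19, Kcnj8, a potassium channel, at 3.12 ± 0.48, As3mt at 2.70 ± 0.59, P3h4 at 2.46 ± 0.50 and Tmprss13 at 2.28 ± 0.48, and the Y-linked Eif2s3y at 3.74 ± 4.31. On the low side the largest were Lcn2 at -5.04 ± 2.39, Chil3 at -5.02 ± 2.91, Lyz1 at -4.70 ± 2.26, Xist at -4.63 ± 4.51, Mgst1 at -4.38 ± 2.72, Lyz2 at -4.24 ± 2.36, Csf2rb at -4.21 ± 2.04, Ifitm6 at -4.11 ± 2.43, Tgfbi at -4.10 ± 2.67 and Cybb at -3.97 ± 2.46. For 7 of these 10 (Lcn2, Xist, Mgst1, Csf2rb, Ifitm6, Tgfbi and Cybb) the SLEC array read under 5.97, the level of the expression filter, so their sizes and ranks are not exact. Most of the 10 are transcripts of myeloid cells, which the MPEC arrays held in both replicates and more in replicate 2. For Lyz2 the difference was -3.08 against replicate 1 and -5.40 against replicate 2. Il7r was at 0.62 ± 0.43 and Cd27 at -0.44 ± 0.42. Foxo1 was at 0.02 ± 0.72, with -0.69 against wild-type replicate 1 and 0.73 against replicate 2, and another of its probe sets went the opposite way.

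Single genes of the memory list lay low in the SLEC array, with St6gal1 at -2.24 ± 0.30, Socs3, a brake on cytokine signalling, at -2.31 ± 0.49, Xcl1 at -1.53 ± 0.27 and Il6ra at -1.27 ± 0.47, but the list went both ways, with 9 genes higher and 13 lower than in both wild-type MPEC arrays. The memory list was not called (adjusted p = 0.75), and 3 of its members passed when adjusted over the list alone. For St6gal1 the SLEC array read under 5.97, the level of the expression filter, so its size is not exact. Of the transcription factors 14 were higher and 15 lower than in both wild-type MPEC arrays, and the low ones included Batf3 at -2.59 ± 0.22, Tox at -1.87 ± 0.37, Irf8 at -1.45 ± 0.24 and Bcl6 at -1.04 ± 0.48. That list had a median of 0.01 and was not called (adjusted p = 0.705), and 3 of its members passed when adjusted over the list alone. Batf3 here and Ccr9 below read 4.52 and 5.33 in the SLEC array, under the filter level of 5.97, so their sizes are not exact. The same limit holds for any other gene whose SLEC reading lies under that level. The list tests used the unshifted values, so a call and a relative median need not go the same way. For NK cell markers, which were not called, the median was -2.30 while the test pointed up. The effector list was called higher (median 0.36, adjusted p = 2.5e-05, and adjusted p = 0.709 with an estimated correlation). Adjustment over this list alone left 2 members, Cx3cr1 and Klrg1. Klrg1 is the marker that set SLECs apart from MPECs in the sort, so its value follows from the gate. The cytotoxic granule list was not called (adjusted p = 0.0776), with the granzymes Gzma at 0.61 ± 0.22 and Gzmk at 0.65 ± 0.25 high but Gzmb at -0.24 ± 0.19 and Lamp1 at -0.25 ± 0.22 low. Foxo1 targets were called higher too (median 0.35, adjusted p = 2.7e-04; adjusted p = 0.709 with an estimated correlation), with Trib2 at 1.03 ± 0.26 and Klf3 at 0.99 ± 0.27 high and Bcl6 low. T cell identity genes were higher (median 0.45, adjusted p = 3.0e-04, and adjusted p = 0.709 with an estimated correlation), with Trat1 at 1.70 ± 0.93, Lat at 0.77 ± 0.65 and Thy1 at 0.51 ± 0.33. Their median was 0.19 against wild-type MPEC replicate 1 and 0.65 against replicate 2, which held more myeloid transcripts. How far the myeloid content of the MPEC arrays accounts for lists called higher in SLECs was not tested. Homing receptors (median 0.16, adjusted p = 0.0161), with Cx3cr1 high and Cxcr5 (-1.22 ± 0.49) and Ccr9 (-2.96 ± 1.09) low, and NK cell receptors (adjusted p = 0.0326), with Klrg1, Klre1 and Klrd1 (0.82 ± 0.23) high, were called higher. For the last list the mean was 0.13 but the median -0.07. Adjusted over the list alone, 1 homing receptor (Cx3cr1), 1 NK cell receptor (the sort marker Klrg1) and 2 B cell markers passed. No Foxo1 target, T cell identity or myeloid gene did. B cell markers (median -1.89, adjusted p = 0.0161; Ms4a1 at -3.13 ± 1.5, Cd79b at -1.47 ± 0.26) and myeloid markers (median -2.23, adjusted p = 0.0326) were called lower. None of these 7 calls held with an estimated correlation (smallest adjusted p = 0.709 with an estimated correlation), and the calls for homing and NK cell receptors were each lost without 3 of the 4 MPEC arrays (highest adjusted p = 0.0875 and 0.129). After quantile normalization of the 7 arrays 4 calls were lost, those for effector genes (adjusted p = 0.0842), T cell identity (adjusted p = 0.0863), homing receptors (adjusted p = 0.413) and NK cell receptors (adjusted p = 0.413), and 5 lists not called before were called lower: inhibitory receptors (adjusted p = 0.00475), cell cycle (adjusted p = 0.00599), cytokines and chemokines (adjusted p = 0.0236), glycolysis and hypoxia (adjusted p = 0.0349) and stress (adjusted p = 0.0494). With sex as a block the calls for T cell identity (adjusted p = 0.0865), B cell markers (adjusted p = 0.235) and myeloid markers (adjusted p = 0.153) were lost, and 4 lists were called that were not before: interferon response (adjusted p = 0.00723), cytotoxic granule (adjusted p = 0.0406), cell cycle and ribosomal proteins (adjusted p = 0.0482 each).

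No single gene passed in this comparison: with limma 0 of 10916 genes had an adjusted p under 0.05 (smallest adjusted p = 0.401), and 1346 had an unadjusted p under 0.05, of which 34 were higher and 1312 lower, a split that includes the overall shift. The single SLEC array was assumed to vary like the MPEC arrays, and no SLEC was given a knockout label.

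The last comparison asked whether the knockout arrays lay toward the SLEC profile. Since no gene was called, it used the 100 genes with the largest SLEC values in each direction, a choice made after seeing the data. In the CD27hi pair the genes high in SLECs had a median difference of -0.15 (percentile 0 of 10000 matched random lists) and the genes low in SLECs 0.10 (percentile 97.9). With genes chosen without wild-type MPEC replicate 1 these medians were -0.04 and 0.03, and without replicate 2 -0.22 and 0.16. In MPECs each pair was set against SLEC genes chosen with the wild-type array of the other pair, so that the contrasts shared no array. Pair 2 then had a median of 0.37 over the genes high in SLECs (percentile 100) and 0.08 over the genes low in SLECs (percentile 100), and pair 1 had 0.21 (percentile 100) and -0.79 (percentile 0). The myeloid markers, low in SLECs, had medians of -1.11 in pair 1 and 0.29 in pair 2. With shared wild-type arrays the correlation of the SLEC and knockout-label differences across genes was 0.312 with a covariance of 0.0327. Unchanged groups simulated against shared controls gave 0.410 and 0.0938, but with every array drawn independently. Same-numbered MPEC arrays deviated together (r = 0.868 across genes), so the simulated values are no fitting baseline and nothing is drawn from them. Between contrasts that shared no array the correlation was 0.310 for pair 1 (SLECs against wild-type replicate 2) and 0.0618 for pair 2 (SLECs against wild-type replicate 1).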

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

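All tests of explanations in this part were chosen after the result was seen. The CD27hi pair lay one way and both MPEC pairs the other for 48 of 114 named genes and 9 of 24 lists. The count of genes depends on how they were named. Some were named because their MPEC arrays did not overlap, so both MPEC pairs agree by choice. Others were named for lying the same way in every pair, so they cannot count as opposite. No share of all genes is given for this count, so whether 48 of 114 is high was not tested. The difference of the 2 effects was tested with limma for the 48 genes and passed for none (smallest adjusted p = 0.313). For the lists this difference was not tested. No group has 4 arrays, so single arrays were not tested as outliers.

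The value given for each gene is the log2 knockout difference of the CD27hi pair minus that of the MPECs. Lower in the CD27hi pair were H2-Ob at -5.81, Cd55 at -4.66, Dapl1 at -4.39, Ms4a6c at -4.29, Vipr1 at -4.26, Il7r at -4.00, Sntb1 at -3.45, Trat1 at -3.31, Gpr183 at -3.31, Cd28 at -3.17, Il6ra at -2.46, Wfikkn2 at -2.45, Trib2 at -2.34, Hs3st3b1 at -2.26, Tnfrsf25 at -2.14, Klrd1 at -2.03, Sesn1 at -1.73, Ccr7 at -1.68, Tmprss13 at -1.44, St6gal1 at -0.83, Bcl2l11 at -0.78, Klf3 at -0.70, Kcnj8 at -0.60 and Pdk1 at -0.24. Higher in the CD27hi pair were Gzma at 4.37, Tbx21 at 4.25, Gzmb at 3.85, Irf8 at 3.30, Xcl1 at 3.23, Lgals3 at 2.94, Cd160 at 2.75, Ccr9 at 2.43, Bcl6 at 1.96, P2rx7 at 1.76, Itih5 at 1.76, Ifitm6 at 1.47, Sema7a at 1.34, Zfp512 at 1.26, Top2a at 1.17, Il2ra at 1.16, Ube2c at 1.06, Serpinb9 at 1.02, Egr3 at 0.90, Klrg1 at 0.80, Cd27 at 0.67, Anxa2 at 0.58, Tnfsf9 at 0.54 and Tox at 0.44. The same difference of list medians was -0.39 for Foxo1 targets, 0.53 for the effector list, 0.48 for cytotoxic granule genes, 0.37 for inhibitory receptors, 0.32 for NK cell receptors, 0.53 for cytokines and chemokines, 0.47 for cytokine receptors and signalling regulators, -0.45 for erythroid and platelet markers and -0.19 for sex-linked genes.

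The opposition of the sorts was weighed against 3 technical explanations. Myeloid or B cells in unequal shares are argued against for the Foxo1 target list, whose median was higher in both MPEC pairs (0.26 and 0.32) although the myeloid list's median was 1.40 log2 higher in pair 2 than in pair 1 and both marker lists changed sign. For single named genes they stay open, since these were taken for lying the same way in both pairs and include Ifitm6 (-2.51 in pair 1). An exchange of genotype labels in both MPEC pairs needs Foxo1 to be higher in both knockout-labelled arrays. It was higher in pair 2 but lower in pair 1 on all 3 probe sets, with a mean of -0.60. That mean lies within the SD of the pairs, but this SD comes from the same 2 values and grows as they disagree. The test therefore cannot decide, and the exchange stays open. An exchange in a single pair was not tested. Resting cells like those of the CD27hi wild-type array, if more frequent in the knockout-labelled MPEC arrays, might raise Il7r and Foxo1 targets; genes at least 8-fold higher in that array had MPEC medians of 0.13 in pair 1 (60.3% of 63 genes higher) and 0.43 in pair 2 (66.1% of 59), too low in pair 1 to decide. A difference between the sorted populations in their need for Foxo1 was not tested, since each sort has its own set of arrays. Nor was a different mix of cells in the CD27hi pair tested, or an absent deletion in the MPEC arrays.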

How the results depend on the processing

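The block for the sex of the arrays, the 100-gene SLEC sets, the 2-fold count shared by the MPEC pairs and the list tests without single arrays were chosen after seeing the data. The counts of 0 genes held under every alternative: 12 for MPECs (smallest adjusted p between 0.547 and 1), 13 over both sorts (0.956 to 1), 13 for SLECs (0.0631 to 0.883) and 7 for the difference of effects (0.184 to 0.474). The planned comparison over genes called in SLECs was not run because none was called. Same-numbered MPEC arrays deviated together (r = 0.868 across genes), but the labels give only shared numbers; with the replicate block 0 genes and 9 lists were called in MPECs (946 genes at an unadjusted p under 0.05), 0 genes over both sorts with the 3 pairs as blocks (442), and 0 in SLECs with sex as a block (4793). In simulated arrays this block recovered 0% of genes changed 2-fold and 38% of those changed 4-fold. With the replicate block the MPEC calls for survival (adjusted p = 0.0515), B cell markers (adjusted p = 0.210) and CD4 markers (adjusted p = 0.125) were not made, and erythroid and platelet markers were called (adjusted p = 0.0261). Adjusted over the list alone with this block, 6 Foxo1 targets, 6 memory genes, 5 transcription factors, 4 homing receptors, 3 cytokines and 3 inhibitory receptors passed. No other list had more than 2. The 6 KLRG1lo arrays allow 10 splits of 3 against 3, too few for a share under 0.05; the real split gave 0 genes and the highest other 1.

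The 204 genes at 2-fold in the CD27hi pair became 659 at 1.5-fold and 66 at 3-fold, since the threshold itself moved; filters and scalings gave 151 to 231. The 14 genes shared by the MPEC pairs became 9 with the 60th percentile filter and 9 with the mean of probe sets, and 13 to 15 otherwise. The correlation of the sorts was negative in all settings, from -0.166 to -0.0659 without single arrays. The CD27hi median over genes high in SLECs was -0.105 with no filter, -0.0735 at the 60th percentile, -0.230 after quantile normalization and -0.224 to -0.0388 without a wild-type MPEC array; over genes low in SLECs it was 0.0257 with no filter, 0.213 at the 60th percentile and 0.0295 to 0.163 without a wild-type MPEC array. With an estimated correlation 0 lists were called in MPECs, 0 over both sorts and 0 in SLECs. Without single arrays 8 to 11, 3 to 6 and 7 to 10 were called. The cause was not tested for these.

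Directions turned for Foxo1 in MPECs with the mean of probe sets (-0.0678) and in SLECs at the 60th percentile (-0.0320), with the mean of probe sets (-0.190), after quantile normalization (-0.0674) and with sex as a block (-0.441), and for Cd27 over both sorts after quantile normalization (-0.0245). Without single arrays the lowest and highest values of the genes that turned were, in MPECs, Foxo1 (-0.749 to 0.771), Cd27 (-0.534 to 0.0941), Ms4a1 (-3.15 to 0.309), Cd74 (-1.88 to 0.797), S100a8 (-2.94 to 0.971), Top2a (-0.609 to 0.107), Ube2c (-0.699 to 0.0437). Over both sorts they were Klrg1 (-0.26 to 0.158), Cd27 (-0.113 to 0.246), Il7r (-0.302 to 0.173), Lcn2 (-2.26 to 0.491), Chil3 (-2.42 to 0.84), Ngp (-2.06 to 0.545), S100a8 (-1.83 to 0.409), Ms4a1 (-1.74 to 0.23), Cd4 (-0.154 to 0.0371), Septin8 (-0.0408 to 1.61), and in SLECs Foxo1 (-0.693 to 0.732). The lists that turned had adjusted p from 1.1e-27 to 0.115 (cell cycle), 7.0e-15 to 0.649 (stress) and 1.1e-10 to 0.297 (B cell markers) in MPECs and from 2.0e-13 to 0.781 (stress) and 7.7e-05 to 0.283 (B cell markers) over both sorts. The cause was not tested. All other values of the named genes kept their direction: 491 in MPECs, 408 over both sorts and 563 in SLECs, and in the CD27hi pair 85 stayed close and 5 moved with the mean of probe sets.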

Other observations

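The tests in this part were chosen after the results were seen. The 2 wild-type KLRG1lo sorts had very different profiles. Differences are given relative to the median gene, since the sets appear to have been normalised apart. The 36 effector genes had a median log2 difference of -4.98 between the CD27hi wild-type array and the wild-type MPECs, the 34 cell cycle genes -3.89 and the 10 NK cell receptor genes -3.34. Gzmb read 6.43 in the CD27hi array and 14.4 on average in the wild-type MPEC arrays, and Gzma 6.77 and 14.2. Single genes, chosen after their values were seen, lay the other way, with Ccr7 at 12.9 against a mean of 6.03, St6gal1 at 13.2 against 6.62 and Bach2 at 12.0 against 7.84, and the memory list had a median of 0.81.

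The heat shock transcript Hspa1a read 9.29 in knockout-labelled MPEC replicate 2 and at most 6.88 on the other 6 arrays. Hspa1b differed by 2.79 in pair 2, where the wild-type array read 8.36, by 0.06 in pair 1 and by 2.43 in the CD27hi pair. In the SLEC array the single genes Pdk1 (-1.65 ± 0.33), Bnip3 (-0.98 ± 0.18) and Tnf (-1.26 ± 0.31) and the activation gene Egr3 (-1.60 ± 0.23) lay low, without passing over all genes. The lists of glycolysis and hypoxia (adjusted p = 0.172; 2 genes higher and 9 lower of 19) and of cytokines and chemokines (adjusted p = 0.333; 2 higher and 9 lower of 16) were not called there.

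The distance of the CD27hi wild-type array from the MPECs in effector genes was weighed against separate normalization. Sorted values of the CD27hi and MPEC wild-type arrays differed by at most 0.936, against an effector median of -4.98. A difference in the scale of whole arrays is thus argued against. After quantile normalization of all 7 arrays the median was -5.07, but that step could not have removed a distance of this size. Effects of separate runs on single probe sets were not tested. The gate and the set of arrays cannot be told apart, since each gate has its own set, and the cell cycle median of -3.89 fits either. No biological explanation beyond the gate was tested.

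The MPEC arrays numbered 2 stood apart from those numbered 1 in 3683 of 10916 genes (limma with genotype as a term, adjusted p under 0.05), 1114 of them higher and 2569 lower. Myeloid cells let through the sort are a candidate source of the higher genes: the myeloid list was at least 1.51 log2 higher in both genotypes, with Lyz2 at 12.9 and S100a8 at 14.1 in wild-type replicate 2 and no gene shared with another list, although a gate on CD8+ OT-I cells would remove them. Other marker lists were higher in replicate 2 as well, by medians in wild-type and knockout-labelled arrays of 1.95 and 3.68 for NK cells (5 genes, some of which myeloid cells express too), 0.09 and 2.00 for B cells and 1.47 and 1.23 for erythroid cells and platelets, so other cells may have added to the difference. The sex of the mice, with Xist 7.43 log2 higher in replicate 2, cannot be told apart from the replicate number.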
